A study of Rattus norvegicus with 4 samples.

How the data were processed

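Total RNA from day 4 rat embryoid bodies was depleted of ribosomal RNA and made into strand-marking TruSeq libraries, sequenced as paired 100 bp reads on a HiSeq, per the labels' protocols. Cells were aggregated in hanging drops of 20 µl for 2 days in medium with CHIR9902 (0.75 µM), the MEK inhibitor PD0325901 (0.1 µM) and the ROCK inhibitor Y27632 (10 µM), then kept on laminin for 24 hours and in a medium named DM for 1 day. Reads were processed with TopHat2 2.0.13 and Cufflinks 2.2.1 on the rn6 rat genome, per the submitters' processing notes, and the annotation is not given in the sources used here. The deposited values are RPKM per gene, 1 table per library, as the authors made them, with a gene identifier, a symbol and a locus in rn6 coordinates.

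Of the 32753 genes, 6893 share a locus with another gene, since such a locus can span a bundle of overlapping genes, and 914 share a symbol. Reads of overlapping genes and of near-identical copies, such as the X and Y copies of Ddx3, Kdm6a and Eif2s3, were divided by the authors' tools in ways the files do not show. Genes outside the protein-coding set took 90.3% to 99.5% of each library's RPKM sum, and genes with a locus under 500 bp took 37.0% to 44.9%. The reason was not tested. Protein-coding genes were picked by symbol or synonym in a RefSeq gene table (assembly GRCr8, used for names and biotypes only), which matched 19341 of the 32753 symbols.

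Differences between Kcnh2-/- and WT were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(RPKM + 1), over the 12355 genes at 1 RPKM or more in at least 2 of the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. The main fit had no replicate term. An exact permutation test of 2 against 2 cannot go below p = 0.333. Gene lists were tested with limma's camera on the same values (preset correlation 0.01) where 5 or more members passed the filter: 32 of 34 lists. The neural crest list had 4 tested members (Erbb3, Ets1, Msx2 and Twist1) and the list of mitochondrially encoded genes matched no name in the files. The test, filter, lists, the rule for named genes and 17 alternatives were fixed before the data were examined; 5 more alternatives and the comparison by chromosome were added later. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the threshold, the correlation within lists, the fry test, a replicate block, each library left out, protein-coding genes alone, and protein-coding genes outside chromosomes 3, 13, 16, X and Y.

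By the rule for named genes, the text names Kcnh2, then in each direction the 10 genes with the largest change past the threshold, with groups that do not overlap, a mean of 5 RPKM or more in the higher group, and no symbol with a prefix listed beforehand (LOC, RGD, AABR, AC0, ENSRNOG, MGC and small-RNA prefixes). Clone names starting with AC1 were not on that list and are therefore named. Fewer than 10 passed in each direction, so the 10 of smallest p that met the other criteria are named. From each list the members of smallest p or highest mean are named. Other genes named were chosen after their values were seen.

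Read depth cannot be had in absolute terms. Ratios between libraries were therefore examined over low genes. Over genes under 0.08 RPKM in both libraries of a pair, 30.4% of 484 genes had a ratio within 1 bin of 0.01 around 0.96 between WT and Kcnh2-/- of replicate 1, and 21.4% of 650 genes around 1.03 for replicate 2. Between libraries of different number the most common ratio held 5.13% to 7.36%. The RPKM sums split by number in the same way. The labels name no batch. Because the files show this split, differences within each replicate number are printed beside the pooled ones, and a fit with the number as a term on protein-coding genes is given as an added alternative.

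For the comparison by chromosome, log2 ratios without a pseudocount were taken over 7730 autosomal and 267 X-linked protein-coding genes at a mean of 5 RPKM or more and above 0 in all 4 libraries, less the autosomal median, with 95% intervals from 1000 bootstrap draws of genes. Genes are not replicates, so these intervals describe the 4 libraries only. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

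The fit was tested on simulated data for Kcnh2-/- against WT, with 200 of the genes changed by known amounts and the spread and replicate effect of the real libraries. Over 12355 genes, the fit with no replicate term recovered 0% of genes changed by a log2 of 1 or 2, 22% at 3 and 62% at 4, with 2 false calls among 44. Over 10850 protein-coding genes with the replicate term it recovered 44% at 1 and 100% at 2 or more, with 10 false calls among 182. Over all 12355 genes with the replicate term, 61 of 232 calls were false. The changed genes had a mean log2(RPKM + 1) of 3 or more, so the rates do not cover low genes such as Kcnh2. Noise was drawn separately for each gene, with no shift of whole chromosomes in single libraries. The simulated data follow the model with the replicate term, so its rate of false calls in the real libraries is not known from them.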

Results

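Gene expression was measured by RNA-seq in rat embryoid bodies, the cell aggregates that pluripotent cells form when they start to differentiate. The series holds 4 libraries. Wild-type (WT) and Kcnh2-/- rat embryonic stem cells were differentiated for 4 days, with 2 libraries per group. The values are RPKM (reads scaled by transcript length and library size) for 32753 genes, between 17610 and 17833 of which were above 0 in each library. Absolute read depth is unknown. The labels do not say whether the replicates came from separate cultures or lines, so the p-values of single genes measure only the spread between these samples. Camera with the preset correlation compares the members of a list with the other genes. Its p-values therefore rest largely on the spread across genes and do not measure how a list varies between libraries. The comparison asks how loss of Kcnh2, which encodes the voltage-gated potassium channel ERG1, alters expression at this early stage, when cells leave pluripotency and the first mesoderm and cardiac genes come on.

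Kcnh2 RNA (rn6 chromosome 4, 7355573 to 7387253) was low in every library and lower in both Kcnh2-/- libraries. It stood at 2.61 and 1.45 RPKM in WT replicates 1 and 2, and at 0.108 and 0.504 RPKM in the matching Kcnh2-/- libraries. The difference in log2(RPKM + 1) was -1.20 ± 0.43 (SE), with a limma adjusted p of 0.980, and was -1.70 within replicate 1 and -0.70 within replicate 2. At these levels the drop did not pass the threshold. The labels do not give the part of the gene that was altered, so RNA abundance checks the genotype only in part.

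Most Y-linked genes were near 0 in both Kcnh2-/- libraries. Eif2s3y (Y, 914044 to 933699), which encodes a translation initiation subunit, was at 144 ± 12.8 RPKM in WT (SD, n = 2) and 0.0985 ± 0.0582 in Kcnh2-/- (SD, n = 2). Its log2 difference was -7.04 ± 0.27 (SE, limma adjusted p = 0.0163). The Y-linked RNA helicase gene Ddx3 (Y, 1217799 to 1238420) was at 60.2 and 42.9 RPKM in WT and at 0.0871 and 0.0102 in Kcnh2-/- (log2 difference -5.63 ± 0.33, adjusted p = 0.0325). Both fell past the threshold. The histone demethylase gene Kdm5d (Y, 505995 to 589267) was at 18.7 and 12.8 RPKM in WT and at 0.00873 and 0 in Kcnh2-/-, and the Y-linked gene listed as Kdm6a was at 5.42 and 6.72 in WT and listed at 0 in both Kcnh2-/- libraries. Neither passed (adjusted p = 0.106 and 0.344). With the replicate term over all genes Kdm5d passed (limma adjusted p = 0.0272) and Kdm6a did not (0.0744). Of the 8 Y-linked genes tested, 7 were higher in both WT libraries than in either Kcnh2-/- library. The exception was the contig-named Rn60_Y_0010.1, at 7.39 and 3.65 RPKM in WT and 4.69 and 1.60 in Kcnh2-/-.

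X-linked genes lay on the other side. Over 267 protein-coding X-linked genes, the median log2 ratio of Kcnh2-/- to WT, less the median over autosomes, was 0.79 within replicate 1 and 0.71 within replicate 2. The medians of the 20 autosomes ran from -0.07 to 0.09 within replicate 1 and from -0.48 to 0.14 within replicate 2, where chromosomes 3, 13 and 16 gave the 3 lowest. This comparison by chromosome was chosen after the data were seen. Among single X-linked genes, Sat1 (X, 43625168 to 43629765), which encodes the rate-limiting enzyme of polyamine breakdown, was at 53.1 ± 5.03 RPKM in WT and 274 ± 4.36 in Kcnh2-/- (SD, n = 2 each), a log2 difference of 2.35 ± 0.24 (adjusted p = 0.183). The purine salvage gene Hprt1 was at 19.6 and 22.8 RPKM in WT and at 88.3 and 60.9 in Kcnh2-/- (adjusted p = 0.837). The deubiquitinase gene Usp26 was at 7.83 and 7.25 against 62.8 and 30.6 (adjusted p = 0.855).

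**Figure D1:**
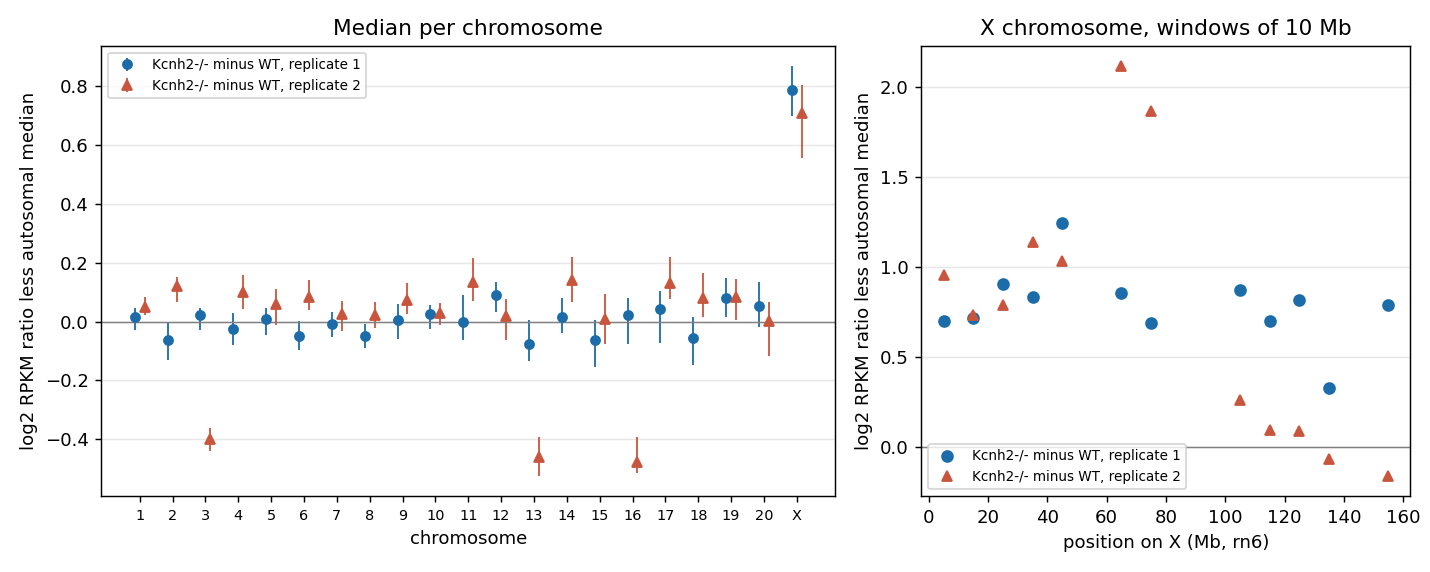
Median log2 RPKM ratio of Kcnh2-/- to WT, less the autosomal median, for protein-coding genes on each chromosome (left, bars are 95% bootstrap intervals over genes) and in windows of 10 Mb along X (right), within replicate 1 (circles) and replicate 2 (triangles). X stands at 0.79 and 0.71, chromosomes 3, 13 and 16 stand apart in replicate 2, and in replicate 2 the level changes along X.

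Over all 12355 genes tested, 418 were at an unadjusted limma p under 0.05, fewer than chance alone would give. After adjustment limma called 14 genes between the groups, 4 higher and 10 lower in Kcnh2-/-. Beside Eif2s3y and Ddx3, the other 12 were listed at 0 in both libraries of one group. These carry contig names or, for Mir299b, a microRNA name, and in the other group they ran from 415 RPKM (AABR07072283.2) to 836212 RPKM (AC120949.1). AC106663.3 (chromosome 14, 86802533 to 86802666), for example, was at 82714 and 43946 RPKM in WT and listed at 0 in Kcnh2-/- (adjusted p = 0.00680). AC111292.2, AC116183.1 and AC103535.2 were likewise listed at 0 in Kcnh2-/- (adjusted p = 0.0325 each). AC120949.1 was listed at 0 in WT and at 836212 and 74253 RPKM in Kcnh2-/- (adjusted p = 0.0446). AC105648.2 and AC134024.2 had the same pattern and missed the threshold (adjusted p = 0.0762 and 0.218), though both passed with the replicate term over all genes (0.00505 and 0.0188). A zero in RPKM files can be a failed estimate, so no fold is given for them.

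Of the other autosomal genes named by the rule fixed beforehand, none passed in the main fit, and the rule itself requires groups that do not overlap. With the replicate term over all genes none passed either (limma adjusted p of 0.0744 or more). With that term and protein-coding genes alone, a setting chosen after the data were seen, all passed (limma adjusted p 0.0120 to 0.0451). Cebpb, a transcription factor of stress and adipocyte differentiation, was at 7.85 and 6.71 RPKM in WT and at 62.9 and 36.3 in Kcnh2-/- (log2 difference 2.56 ± 0.36, adjusted p = 0.502). Aggf1, an angiogenic factor gene, was at 0.755 and 2.00 against 21.5 and 14.8 RPKM, and Ccdc152 at 1.72 and 2.73 against 12.8 and 10.5. The imprinted gene Snrpn was at 60.01 and 62.7 RPKM in WT and 162 and 156 in Kcnh2-/-. Hist2h2ac, a histone H2A gene, was at 455 and 376 RPKM in WT and 130 and 103 in Kcnh2-/-. Leap2, which encodes a ghrelin receptor antagonist, was at 5.38 and 11.6 RPKM in WT and listed at 0 in both Kcnh2-/- libraries. In all, 3954 of the 12355 genes (32.0%) had groups that did not overlap, against the 33.3% that chance gives with 2 against 2.

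The counts of calls moved with the scaling, the set of genes and a replicate term. They were 1 higher and 10 lower after median-of-ratios scaling and 8 higher and 11 lower after quantile normalization. Library properties followed the replicate number in both groups: the RPKM values summed to 7.95e+07 and 1.09e+08 in the replicate 1 libraries and to 1.17e+07 and 8.93e+06 in the replicate 2 libraries, mostly from genes outside the protein-coding set. The labels name no batch. Over the 10850 protein-coding genes alone limma called 0 genes higher and 3 lower, and with the replicate number as a term as well it called 57 higher and 25 lower. Both settings were chosen after the data were seen.

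**Figure D2:**
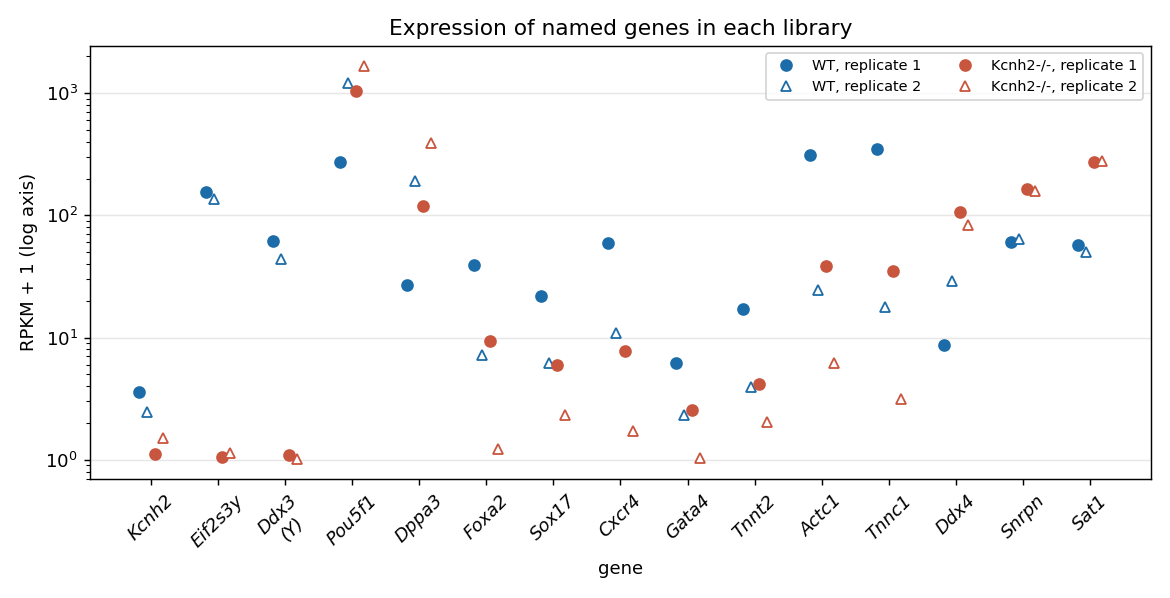
RPKM + 1 of named genes in each library (log axis), with circles for replicate 1, triangles for replicate 2, blue for WT and red for Kcnh2-/-. Eif2s3y and Ddx3 stand near the floor in both Kcnh2-/- libraries, and Actc1 and Tnnc1 are lower in Kcnh2-/- within each replicate number and lower in replicate 2 within each group.

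Genes of the endoderm, the primitive streak and muscle were lower in Kcnh2-/- as lists. Of the 32 gene lists tested, camera with a preset correlation of 0.01 called 13, of which 7 fell and 6 rose. The definitive endoderm list fell (median log2 difference -1.10 over 11 members, adjusted p = 0.00221, and adjusted p = 0.596 with an estimated correlation), with medians of -1.41 within replicate 1 and -0.92 within replicate 2. Its members include Foxa2, a pioneer transcription factor of endoderm, at 38.3 and 6.18 RPKM in WT and 8.37 and 0.231 in Kcnh2-/-. The chemokine receptor gene Cxcr4 was at 58.1 and 10.0 against 6.71 and 0.726, and Sox17 at 20.8 and 5.15 against 4.96 and 1.32. The primitive streak and mesendoderm list fell (median -1.24 over 9, adjusted p = 0.0114, and adjusted p = 0.596 with an estimated correlation), with -0.89 and -1.74 within replicates 1 and 2. In it, Lhx1 was at 6.11 and 2.74 RPKM in WT and 1.67 and 0 in Kcnh2-/-. The Nodal and Wnt antagonist gene Cer1 was at 52.2 and 28.8 against 21.4 and 0.144, while Nodal was at 16.1 and 44.9 against 35.0 and 87.2. The extraembryonic endoderm list fell as well (median -0.95 over 16, adjusted p = 0.0114, and adjusted p = 0.596 with an estimated correlation), with -1.42 and -0.52 within replicates. Of its members, 11 were lower and 2 higher in Kcnh2-/- within both replicate numbers, a pairing that the labels do not give. Without that pairing, 3 of the 16 were lower with groups that did not overlap, against 1891 of all 12355 genes tested. Gata4 was at 5.19 and 1.32 RPKM in WT and 1.54 and 0.0265 in Kcnh2-/-, while Apoa2 was at 2.10 and 14.7 against 12.8 and 23.4. Foxa2 and Lhx1 are in both the definitive endoderm and the primitive streak list, and Sox17 is in both endoderm lists. Lamc1 is in the extraembryonic endoderm and the extracellular matrix list. The falls of these lists are therefore not separate findings. Without WT replicate 1 the median was -0.0772 for extraembryonic endoderm (adjusted p = 0.930), -0.42 for definitive endoderm (0.410) and -0.76 for primitive streak and mesendoderm (0.358). Without Kcnh2-/- replicate 2 the medians of these lists were, in the same order, -0.54, -0.78 and -0.69. At their lowest across the alternatives they were -1.86, -2.00 and -2.06. The call of the primitive streak and mesendoderm list was lost with the filter at 5 RPKM (median -1.11, adjusted p = 0.279).

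The cardiomyocyte list fell with a median of -1.09 over 10 members (adjusted p = 0.0331, and adjusted p = 0.596 with an estimated correlation), and by replicate number the medians were -1.77 and -0.49. The list holds 31 genes, of which these 10 passed the filter. Only 1 of the 10 was lower in Kcnh2-/- with groups that did not overlap, against 1891 of all 12355 genes tested. Cardiac troponin C (Tnnc1) was at 349 and 16.6 RPKM in WT and at 34.2 and 2.15 in Kcnh2-/-, and cardiac actin (Actc1) at 310 and 23.5 against 37.3 and 5.14. Cardiac troponin T (Tnnt2) was at 16.1 and 2.91 against 3.15 and 1.04, and the gap junction gene Gja1 at 52.4 and 68.7 against 31.8 and 39.9. The cardiomyocyte median was 0.10 without WT replicate 1 (adjusted p = 0.864), -0.27 without Kcnh2-/- replicate 2 (0.391) and -0.74 (adjusted p = 0.182) without genes of chromosomes 3, 13, 16, X and Y, which leaves out Tnnc1, Actc1 and Tnnt2. The smooth muscle list fell (median -0.89 over 10, adjusted p = 0.0484, and adjusted p = 0.727 with an estimated correlation; -1.21 and -0.33 within replicates), with Tagln at 1329 and 54.9 RPKM in WT and 255 and 16.7 in Kcnh2-/-. The smooth muscle call was lost, at a similar median, with median-of-ratios scaling (-0.90, adjusted p = 0.0709), quantile normalization (-0.996, 0.0694) and without those chromosomes (-0.82, 0.0709). The smooth muscle median was 0.0520 without WT replicate 1 and -0.24 without Kcnh2-/- replicate 2. Extracellular matrix and adhesion genes fell (median -0.54 over 25, adjusted p = 0.00371, and adjusted p = 0.596 with an estimated correlation; -0.77 and -0.44), including fibronectin (Fn1) at 130 and 126 against 48.4 and 70.8 RPKM. Without WT replicate 1 the extracellular matrix and adhesion median was -0.21 (adjusted p = 0.410). Wnt target genes fell (median -0.59 over 12, adjusted p = 0.0172, and adjusted p = 0.596 with an estimated correlation; -1.14 and -0.70). In this list the Wnt antagonists Sfrp1, at 15.4 and 8.88 against 4.17 and 1.48, and Sfrp2, at 4.76 and 4.36 against 0.706 and 1.53, had the smallest p, while Axin2 was at 2.39 and 4.62 against 5.66 and 5.94. The median of Wnt targets was -0.49 without genes of chromosomes 3, 13, 16, X and Y (adjusted p = 0.126), -0.22 without WT replicate 1 (0.504) and -0.35 with the filter at 5 RPKM (0.679).

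Metabolic, stress and germ cell genes were higher in Kcnh2-/- as lists. Nuclear genes of oxidative phosphorylation rose (median 0.42 over 25, adjusted p = 1.49e-05, and adjusted p = 0.596 with an estimated correlation; 0.30 and 0.67 within replicates), with the X-linked Ndufa1 at 90.7 and 130 RPKM in WT and 185 and 270 in Kcnh2-/- and Ndufv2 at 88.9 and 75.2 against 117 and 172. Cholesterol synthesis genes rose (median 0.55 over 21, adjusted p = 4.82e-05, and adjusted p = 0.596 with an estimated correlation; 0.33 and 0.56), including Hmgcs1 at 119 and 122 against 159 and 232 RPKM. The integrated and ER stress list rose (median 0.28 over 25, adjusted p = 0.00237, and adjusted p = 0.596 with an estimated correlation; 0.20 and 0.43). The serine synthesis gene Psat1 was at 122 and 108 against 229 and 184 RPKM. p53 target genes rose (median 0.36 over 25, adjusted p = 0.00398, and adjusted p = 0.596 with an estimated correlation; 0.37 and 0.58), with Mdm2 at 90.2 and 100 against 140 and 219 RPKM. Ribosomal protein genes rose (median 0.31 over 29, adjusted p = 0.0214, and adjusted p = 0.804 with an estimated correlation; 0.18 and 0.38), led by the X-linked Rps4x at 1485 and 1505 against 2776 and 9971 RPKM. Rps4x (X, 72074107 to 72078551) lies at 60 to 80 Mb, a part of X that stood higher as a whole in Kcnh2-/- replicate 2, as described below. The germ cell and 2-cell-like list rose (median 0.80 over 14, adjusted p = 0.0144, and adjusted p = 0.596 with an estimated correlation; 1.13 and 0.30), with the germline helicase gene Ddx4 at 7.75 and 27.9 against 105 and 81.9 RPKM and Sycp3, of the meiotic chromosome axis, at 1.32 and 6.43 against 12.6 and 19.8. Quantile normalization moved the median of integrated and ER stress to 0.20 (camera adjusted p = 0.0527). It moved that of oxidative phosphorylation to 0.17 (adjusted p = 0.0564) and that of ribosomal proteins to -0.0350 (0.887). Without Kcnh2-/- replicate 2 they stood at 0.24 (adjusted p = 0.0773) and 0.0688 (0.601), with the germ cell and 2-cell-like list at 0.48 (0.0925), p53 targets at 0.16 (0.0925) and cholesterol synthesis at 0.31 (0.0735). Without WT replicate 1 ribosomal proteins stood at 0.14 (adjusted p = 0.602) and the germ cell and 2-cell-like list at 0.24 (0.410), and the filter at 5 RPKM left the latter at 0.80 (0.0570).

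None of the 13 calls held when the correlation was estimated from the data. The power of that form of the test with 2 libraries per group was not measured. The same adjusted p of 0.596 recurred across most of the 13 lists through the adjustment over lists. Before adjustment, camera p with an estimated correlation ran from 0.0619 (extracellular matrix and adhesion) to 0.522 (ribosomal proteins) over the 13. The loss of a call in that form therefore cannot decide for or against a single list. The fry test called 0 of the 32 lists as well. Without Kcnh2-/- replicate 2 no list was called, and without WT replicate 1 the 3 lists called were oxidative phosphorylation, cholesterol synthesis and integrated stress. Lists also differed between replicates of one group: the cardiomyocyte median was lower in replicate 2 than in replicate 1 by 2.61 in WT and by 1.22 in Kcnh2-/- on the log2 scale, and naive pluripotency was higher in replicate 2, by 1.93 and 1.37. Replicate 2 minus 1 was -0.95 in WT and -1.09 in Kcnh2-/- for definitive endoderm, near its group difference of -1.10. For extraembryonic endoderm it was -1.76 and -1.16, against a group difference of -0.95. Extracellular matrix and adhesion moved less, by -0.39 and -0.15, against -0.54. No member of any of the 13 lists passed alone, either over all genes tested or adjusted over the list alone. With protein-coding genes and the replicate term, members passed in definitive endoderm (2 lower over all genes tested, 7 adjusted over the list alone), cardiomyocyte (3 and 6), and extraembryonic endoderm (0 and 8, with 1 member higher adjusted over the list alone), among others. In the germ cell and 2-cell-like list 1 was higher over all genes tested, and 6 were higher and 2 lower adjusted over the list alone.

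**Figure D3:**
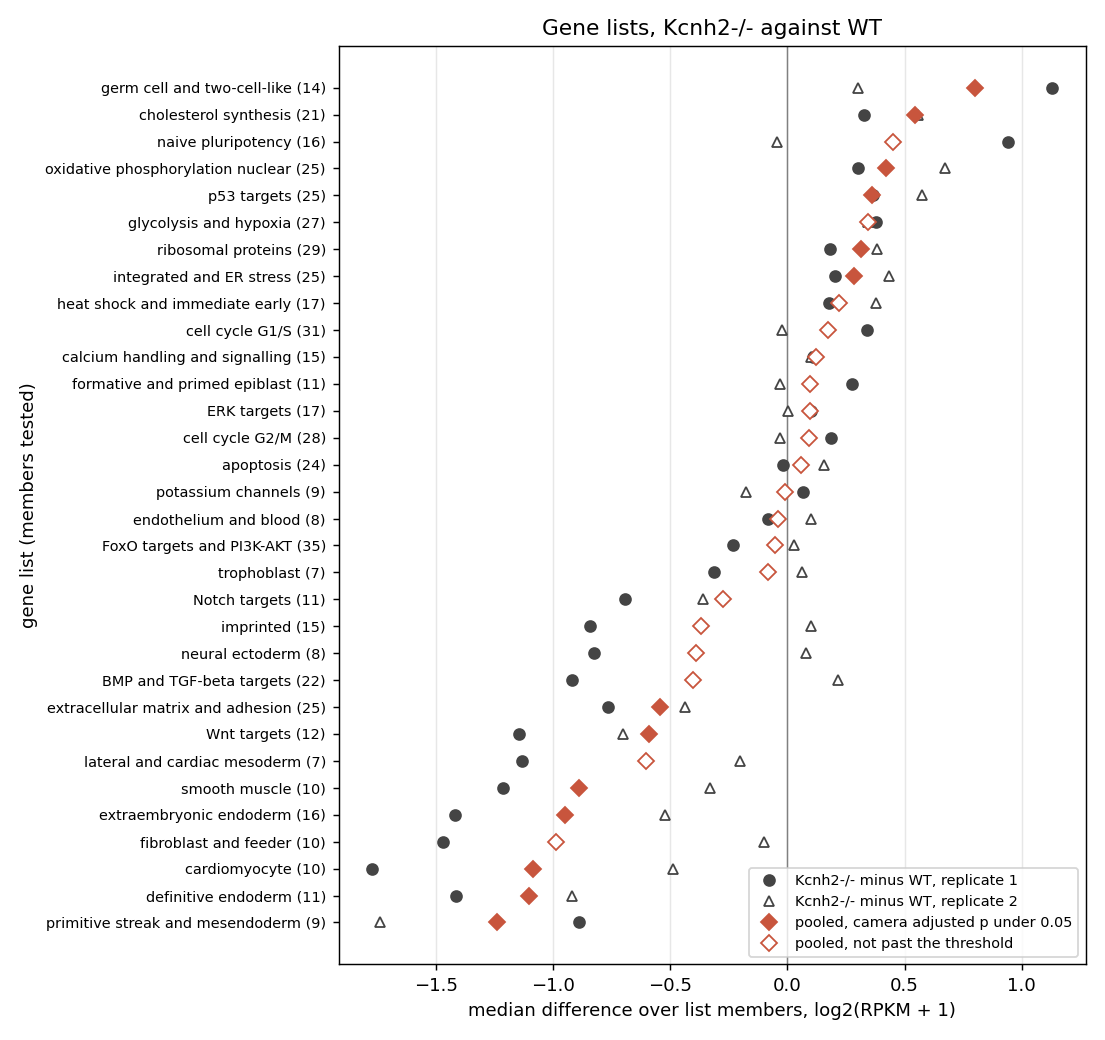
Median difference of each gene list, Kcnh2-/- minus WT in log2(RPKM + 1), pooled (diamonds, filled where camera gave an adjusted p under 0.05) and within replicate 1 (circles) and replicate 2 (triangles). Definitive endoderm stands at -1.10 and oxidative phosphorylation at 0.42 pooled, and cardiomyocyte genes at -1.77 and -0.49 within replicates.

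Pluripotency genes did not pass as a list (naive pluripotency, median 0.45 over 16, adjusted p = 0.468), and the within-replicate medians of 0.94 and -0.05 lay on opposite sides of 0. The naive pluripotency call depended on single libraries: it passed without WT replicate 2 (median 1.72, adjusted p = 0.00153) and without Kcnh2-/- replicate 1 (0.97, adjusted p = 0.0295), and its median was -0.75 without WT replicate 1 (adjusted p = 0.160). Pou5f1 (Oct4) was at 273 and 1203 RPKM in WT and 1043 and 1679 in Kcnh2-/-, and Fgf4 at 5.45 and 15.3 against 19.4 and 39.8. The formative and primed epiblast list did not pass either (adjusted p = 0.759), with Dnmt3b at 430 and 1016 against 1174 and 618 RPKM. Lateral and cardiac mesoderm genes had a median of -0.60 over 7 (adjusted p = 0.102), of which Gata6 was at 6.07 and 0.804 against 1.05 and 0.406 RPKM. Across the alternatives the median of this list ran from -1.66, without WT replicate 2, to -0.0314. With no filter on low values camera with the preset correlation called it (-0.54, adjusted p = 0.00022). The PI3K-AKT and FoxO list, the pathway of insulin and growth factor signalling, had a median of -0.05 over 35 (adjusted p = 0.613). In it Pik3r1 was at 7.12 and 7.80 against 14.3 and 17.4 RPKM and Igf1r at 6.43 and 5.81 against 2.13 and 3.32. Potassium channel genes (median -0.01 over 9, adjusted p = 0.623) and calcium handling genes (median 0.12 over 15, adjusted p = 0.954) did not pass.

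The imprinted list was not called (median -0.37 over 15, adjusted p = 0.431), but 3 members at 2 loci passed when adjusted over the list alone: Snrpn and Snurf, which share a locus, higher, and Nnat lower, at 99.6 and 51.3 RPKM in WT and 18.6 and 20.9 in Kcnh2-/- (adjusted p = 0.0368 each). None of them passed over all genes tested in the main fit. Without WT replicate 2 the median of the imprinted list was -1.02. Of markers of other cell types, fibroblast and feeder genes (median -0.99 over 10, adjusted p = 0.283), neural ectoderm (median -0.39 over 8, adjusted p = 0.283), trophoblast (median -0.08 over 7, adjusted p = 0.825) and endothelium and blood (median -0.04 over 8, adjusted p = 0.730) did not pass. Nor did glycolysis and hypoxia (adjusted p = 0.0647), Notch targets (0.0836), cell cycle G1/S (0.149), BMP and TGF-beta targets (0.149), heat shock and immediate early genes (0.321), cell cycle G2/M (0.431), apoptosis (0.907) or ERK targets (0.954). With protein-coding genes and the replicate term, fibroblast and feeder genes (adjusted p = 0.0106), lateral and cardiac mesoderm (0.00623) and glycolysis and hypoxia (0.00130) were called as well. With the replicate term over all genes each had an adjusted p = 0.646 with an estimated correlation, a value that most lists share. Across the alternatives the fibroblast and feeder median ran from -1.73, without WT replicate 2, to 0.60. Median, mean and test differed in sign for endothelium and blood, apoptosis, calcium handling and ERK targets.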

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

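Kcnh2 stayed lower in Kcnh2-/- and missed the threshold under all 16 alternatives that gave it a value (log2 difference -2.53 to -0.40, adjusted p 0.223 to 1.00; the filter at 5 RPKM left it out), and the X-linked excess over the autosomes stayed positive (0.26 to 0.79). The count of genes called did not hold. The counts at an unadjusted p under 0.05 given in this part were fewer than chance alone would give. Against 4 higher and 10 lower, limma gave 7 and 11 with a pseudocount of 0.1, 0 and 3 with a pseudocount of 5, 0 and 1 with no filter on low values (20201 genes, 631 at an unadjusted p under 0.05), 1 and 10 with median-of-ratios scaling, 8 and 11 with quantile normalization, 0 and 3 without the variance trend, and 7 and 11 at an adjusted p under 0.10. Leaving out each library gave 0 to 9 higher and 3 to 10 lower: 0 and 10 without WT replicate 1 or 2, 9 and 3 without Kcnh2-/- replicate 1, 9 and 7 without Kcnh2-/- replicate 2. There the lone library is assumed to vary like the other group. The replicate block gave 14 higher and 14 lower and 16 lists, adding fibroblast and feeder (adjusted p = 0.0299), lateral and cardiac mesoderm (0.00759) and glycolysis and hypoxia (0.00730), each with an adjusted p = 0.646 with an estimated correlation. Only 2 pairs exist and the labels do not say that a number is shared, while the differences of replicate 2 from 1 in WT and in Kcnh2-/- had a correlation of 0.38 across genes (not independent replicates).

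Settings chosen after seeing the data gave 0 higher and 3 lower with protein-coding genes only, 57 and 25 with protein-coding genes and the replicate block, 0 and 1 for protein-coding genes outside chromosomes 3, 13, 16, X and Y (239 at an unadjusted p under 0.05), and 30 and 14 when these also had the replicate block. Of gene lists, 13 were called as planned, 8 after quantile normalization, 0 with an estimated correlation, with or without the replicate block, 0 with the fry rotation test, and 0 to 21 when a library was left out (3 without WT replicate 1, 21 without WT replicate 2, 16 without Kcnh2-/- replicate 1 and 0 without Kcnh2-/- replicate 2). The direction turned for cardiomyocyte (median 0.10) and smooth muscle (0.0520) without WT replicate 1, and for ribosomal proteins after quantile normalization (-0.0350). Without WT replicate 2 the medians of cardiomyocyte and smooth muscle were -2.47 and -1.48. The cause was not tested.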

Other observations

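The tests in this part were chosen after the results were seen, except the replicate block over all genes and the planned test of Kcnh2. With protein-coding genes and the replicate number as a term, 82 genes passed (limma adjusted p under 0.05). With the replicate block over all genes only 7 of them passed, and of those named here Cox7b2 and Tex11 (adjusted p = 0.00505 and 0.0415) did. Among the 57 that rose in Kcnh2-/- were the germline helicase gene Ddx4 (log2 difference 2.56) and the meiotic genes Tex11 (X, 4.06) and Tex12 (2.42). The transcription factor gene Sohlh2 (2.11) and the immunophilin gene Fkbp6 (2.41) rose as well. Tex11 (X, 70670321 to 70946565) lies in the part of X at 60 to 80 Mb that is described below for Kcnh2-/- replicate 2. Cox7b2, a subunit gene of cytochrome oxidase, was at 1.62 and 12.4 RPKM in WT and at 56.2 and 346 in Kcnh2-/-. The quinone reductase gene Nqo1, at 40.4 and 189 against 191 and 554 RPKM, the glutathione transferase gene Gstp1, at 536 and 2006 against 2485 and 4924, and the autophagy receptor gene Sqstm1, at 159 and 191 against 409 and 499, also passed, as did the arginine transporter gene Slc7a3 (X) at 71.6 and 133 against 352 and 714. Slc7a3 (X, 70972764 to 70978952) lies in the same part of X as Tex11. Of the 82 genes, 24 lie on X, all of them higher, which is 29.3% against 3.31% of the genes tested (two-sided Fisher's exact test, odds ratio 12.9, p = 7.84e-17, with genes not independent).

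Genes that fell in the same fit include the sarcomere genes Tnnc1 (log2 difference -2.90), Actc1 (-2.51) and Acta1 (-1.65), the endoderm genes Cxcr4 (-2.80) and Foxa2 (-2.31), and the Nodal co-receptor gene Cfc1, at 61.1 and 7.35 RPKM in WT and 8.88 and 0.405 in Kcnh2-/-. The growth factor gene Fgf10 was at 21.3 and 5.78 against 4.36 and 0.308, the ERK antagonist gene Spry1 at 35.7 and 9.63 against 7.10 and 2.36, and the cyclin gene Ccnd2 at 76.4 and 3.60 against 7.02 and 0.327 RPKM. The RNA-binding protein gene Mex3a was at 3021 and 1748 against 998 and 550 RPKM, and the imprinted gene Nnat also fell. Of the 25 genes lower in this fit, 15 had groups that did not overlap, against 53 of the 57 higher. For Tnnc1, Actc1, Acta1, Foxa2, Cfc1 and Ccnd2, WT replicate 2 lay below Kcnh2-/- replicate 1. Each had a limma adjusted p of 0.980 in the main fit, so these calls rest on the replicate term, which the labels do not give as a pair.

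The median of X-linked genes was higher and protein-coding Y-linked genes were near 0 (at most 0.140 RPKM) in both Kcnh2-/- libraries. The lower of the X-linked medians, 0.71, lies above every autosomal median. Scaling or composition of a whole library was taken out with the autosomal median, so these values do not test it. The levels of replicate 1 are consistent with 2 active X chromosomes and no Y in the Kcnh2-/- cells, against 1 X and 1 Y in WT, with an X-linked median of 0.79 near the log2 of 1 that a doubling gives, while in replicate 2 the median of 0.71 mixes parts of X at 0.86, 2.11 and 0.0584. An effect of the loss of Kcnh2 cannot be told apart from it, since 0 of the Kcnh2-/- libraries keep Eif2s3y expression, nor can a swap of both pairs of libraries, which would leave the same Eif2s3y ratio of 967 but would reverse Kcnh2, at 2.61 and 1.45 RPKM in WT and 0.108 and 0.504 in Kcnh2-/- (adjusted p = 0.980). As a hypothesis, the WT and Kcnh2-/- cells may be lines of different sex, in which case every difference between the groups also compares XX-like with XY cells.

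In WT replicate 2, genes of chromosomes 3, 13 and 16 were higher than in WT replicate 1, by medians of 0.35, 0.38 and 0.41. A batch that follows the replicate number is argued against, since in Kcnh2-/- these medians moved by at most 0.0751 between replicates. Scaling of a whole library was taken out with the autosomal median, so these values do not test it. The 3 chromosomes were singled out after their values were seen. Within replicate 2 the highest of their medians of Kcnh2-/- minus WT was -0.40, while the other autosomes lay between 0.00330 and 0.14. Kcnh2-/- minus WT in replicate 2 ran from -0.67 to -0.26 in the 35 windows of 10 Mb along the 3 chromosomes, while 58 of 206 windows of the other autosomes were below 0 and 1 of them was at or below -0.26; WT replicate 2 minus 1 was above 0 in 34 of the 35 and in 57 of the 206, from -0.35 to 0.79 along the 3 chromosomes. Extra copies of these chromosomes in WT replicate 2 cells may explain most windows, but the window at -0.35 (chromosome 3, 30 to 40 Mb) is not accounted for, and no biological explanation from the design was tested.

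In Kcnh2-/- replicate 2, X-linked genes stood at 3 levels. The 99 genes at 0 to 50 Mb had a median of 0.86 over WT, close to the 0.79 of replicate 1, the 52 genes at 60 to 80 Mb had 2.11 against 0.80, and the 107 genes at 100 to 160 Mb had 0.0584 against 0.79. A batch of the replicate number is argued against by the WT libraries, where genes at 60 to 80 Mb moved by -0.27 from replicate 1 to 2, and inactivation of a whole X by the same genes, which were higher by 1.02 in Kcnh2-/- replicate 2 than in replicate 1. Gain of a part of X and loss of another part, down to the level of 1 copy (0.0584), is a candidate explanation. No biological explanation from the design was tested.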
